A study of Homo sapiens with 12 samples.

How the data were processed

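RNA sequencing libraries from human mesenchymal stem cells, derived from induced pluripotent stem cells, were compared with and without induction of 3 constructs. Per the labels, each of 3 cell lines carried 1 construct under doxycycline control: the HEY1-NCOA2 fusion, HEY1, or NCOA2. Each line gave 2 uninduced libraries and 2 libraries from cells given 50 ng/ml doxycycline for 24 h, 12 libraries in 6 groups of 2. Groups were taken from the labels of each sample. Nothing in the labels says that the replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical. No line that received doxycycline without a coding construct is labelled, so an effect of doxycycline itself is part of each induction effect.

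Per the labels' protocols, libraries were made with a stranded polyadenylated RNA kit. Per the submitters' processing notes, Trim Galore, STAR 2.7.1a, GATK 4.0.4.0 and RSEM were used with human genome builds hg38 and GRCh38.p12; the role of each tool is not stated, and neither is whether counting was strand-specific. The deposited expected counts are RSEM estimates per gene without normalization, and 3.26% of all values in the table are not whole numbers. The deposited TPM values are RSEM values that the authors scaled by transcript length and library total. A deposited table of FPKM values for the same genes and libraries was not used, since it adds no measurement.

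The count table holds 60754 entries, of which 92 are ERCC spike-ins at 0 in every library and were left out, which leaves 60662 genes. Gene symbols were taken from the deposited identifiers, and coordinates (1-based, GRCh38) and gene types from GENCODE release 29, in which 58587 identifiers matched without and 43963 with their version. Each library held between 61418808 and 112244723 assigned counts. Counts were rounded to whole numbers, which changed a library's total by at most 2.39e-05 percent. Genes with low counts in all groups were removed with filterByExpr, which left 18183 tested genes, 14132 of them protein coding. Libraries were scaled with TMM factors, and 1 model with a mean per group was fitted to all 12 libraries with edgeR 4.0.16 (robust quasi-likelihood, 6 residual degrees of freedom) in R 4.3.3. The 5 contrasts tested were induced minus uninduced in each of the 3 lines, and the fusion's induction effect minus that of HEY1 or of NCOA2. The 3 uninduced groups were compared with an F-test. All tests were two-sided, and p-values were adjusted over the tested genes by the Benjamini-Hochberg method with a threshold of 0.05. Rose, fell, higher and lower refer to genes past this threshold. Log2 changes are given with their standard error, which is the change divided by the root of the F statistic, and levels as mean CPM ± SD of the 2 libraries of a group, where CPM are counts relative to the library total after scaling with the TMM factors.

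The comparisons with their tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined; tests of explanations were added later. The gene lists, 51 in number, were written from textbook knowledge of pathways, cell types and cell functions and hold 1244 symbols, matched to 1216 genes; 50 lists had at least 5 tested members. Lists were tested within a contrast with camera (limma 3.58.1, inter-gene correlation 0.01), which compares a list with all other genes, and adjusted over the 50 lists. The test was repeated with the correlation estimated from the data, and with fry, which asks whether a list's genes move on balance in 1 direction. Genes named are, per contrast, up to 10 with the highest and 10 with the lowest log2 change among protein-coding genes past the threshold with a mean of at least 5 CPM in at least 1 group, for inductions also with both induced libraries on the same side of both uninduced ones; 20 genes fixed in advance; and for lists described, the 4 members with the smallest adjusted p and those called against the list's direction. Some of the genes that this rule names are not reported here. Larger overlaps with exons of another annotated gene are pointed out for the genes described first, since reads from the overlap may be assigned to either gene.

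Where a group had 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the 2 libraries of the group. For 1 to 3 counts, the ratio is given with its 95% counting interval. Floors and intervals cover counting error only. Simulated counts took the real uninduced means and library sizes, and 200 genes with a mean above 1 CPM were changed in 1 comparison. Their spread was the fitted trend with expression level, the same in all groups. Genes or groups with a larger spread were thus not covered. For the fusion's induction (17442 genes, 10 false calls) the test recovered 95.6% of 1.5-fold changes, 93.9% of 2-fold changes and 100.0% of 4-fold changes. For the HEY1 induction it recovered 92.6%, 93.9% and 98.5% (17439 genes, 14 false calls), and for the NCOA2 induction 97.1%, 100.0% and 100.0% (17435 genes, 14 false calls).

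The 11 alternatives besides leaving out each library in turn were RLE size factors, no filter on low counts, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, limma-trend on TPM values with a pseudocount of 1 or 0.1 (genes with a mean TPM of at least 0.5), fits to the libraries of the compared lines alone, the replicate number as a block in 2 forms, and a test against a 1.2-fold change (glmTreat).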

Results

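The data are RNA sequencing counts from human mesenchymal stem cells, grown from induced pluripotent stem cells, in which doxycycline switched on 1 of 3 constructs. HEY1 is a transcriptional repressor induced by Notch signalling, NCOA2 is a coactivator of nuclear receptors, and the HEY1-NCOA2 fusion joins them; the series title names mesenchymal chondrosarcoma, the tumour in which this fusion is known. Each of the 6 groups, 3 lines with and without doxycycline, held 2 libraries. Assigned counts per library were 112244723 and 106680943 for the uninduced and 86315617 and 87680145 for the induced fusion line. They were 83420771 and 61418808 for the uninduced and 67138503 and 70058712 for the induced HEY1 line. In the NCOA2 line they were 87730912 and 92077207 uninduced and 110901374 and 87677623 induced. Log2 CPM correlated across genes between the 2 libraries of a group with r between 0.992 and 0.995. The libraries of each pair differed by more than sampling noise, with chi-square per degree of freedom from 3.77 for uninduced NCOA2 to 19.2 for induced HEY1. In a principal component analysis, the first component held 52.7% of the variance and parted the 2 induced fusion libraries (110 and 111) from the other 10 (-27.9 to -10.6). Transcripts of the mitochondrial genome took 2.12% to 4.11% of the counts of a library.

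The constructs were measured first, since their genes check the labels. In the fusion line HEY1 rose from 0.641 ± 0.0426 to 55.9 ± 2.02 CPM and NCOA2 from 24.5 ± 2.51 to 418 ± 9.01 CPM. In the HEY1 line HEY1 rose from 4.04 ± 0.555 to 507 ± 55.4 CPM while NCOA2 stood at 20.3 and 18.6 CPM. In the NCOA2 line NCOA2 rose from 23.7 ± 0.670 to 827 ± 67.3 CPM while HEY1 stood at 0.266 and 0.246 CPM. The log2 changes of HEY1 (ENSG00000164683.17, chromosome 8, 79764010 to 79767863) were 6.44 ± 0.11 with the fusion (adjusted p = 5.13e-16), 6.96 ± 0.09 with HEY1 (adjusted p = 6.53e-16) and -0.10 with NCOA2 (adjusted p = 0.939). Those of NCOA2 (ENSG00000140396.13, chromosome 8, 70109762 to 70403805) were 4.09 ± 0.07 (adjusted p = 6.56e-17), -0.12 (adjusted p = 0.316) and 5.13 ± 0.08 (adjusted p = 9.56e-17). On the TPM scale HEY1 reached 135 ± 8.79 in the induced fusion line and 840 ± 95.0 in the induced HEY1 line. NCOA2 reached 338 ± 12.3 in the induced fusion line and 440 ± 26.3 in the induced NCOA2 line. These values use the lengths of the separate genes, which differ from that of the fusion transcript. In the induced fusion line, reads of the fusion transcript are assigned to the separate genes in an unknown split, so its values are not levels of native HEY1 or NCOA2 and cannot be ranked against those of the other lines. In each line the genes of its own construct rose, and the gene of another construct did not pass the test.

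**Figure D1:**
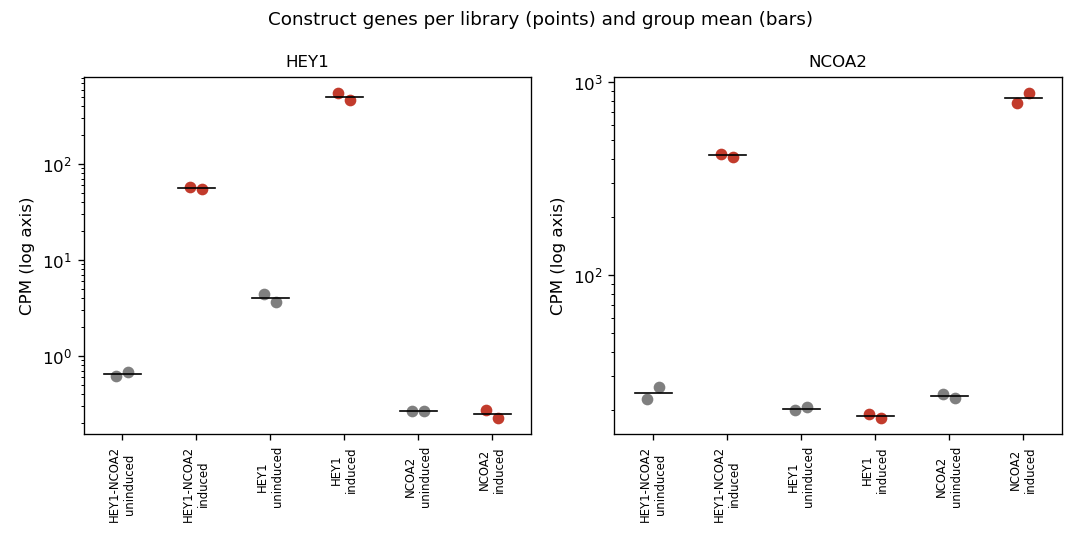
HEY1 (left) and NCOA2 (right) in each library, in CPM on a log axis, by line and induction; points are libraries and bars the mean of the 2 libraries of a group. HEY1 stood at 55.9 CPM in the induced fusion line and 507 CPM in the induced HEY1 line, and NCOA2 at 418 CPM and 827 CPM in the induced fusion and NCOA2 lines.

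The lines were first compared without induction. HEY1 was already higher in the HEY1 line than in the NCOA2 line (log2 difference 3.93 ± 0.19, adjusted p = 1.14e-09). It was higher in the fusion line too (1.26 ± 0.26, adjusted p = 0.0015). Of 18183 tested genes, 8022 differed among the 3 uninduced lines. The uninduced fusion and HEY1 lines differed in 1035 genes (571 higher and 464 lower in the fusion line), and the uninduced NCOA2 line differed from the fusion line in 7124 and from the HEY1 line in 6735. Each induction was therefore measured within its line. With 1 line per construct, differences between constructs may stem from the lines.

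Induction of the fusion, which asks for the genes the fusion changes, gave its highest changes in genes at low levels in uninduced cells. LEF1, a transcription factor of the Wnt pathway (ENSG00000138795.10, chromosome 4, 108047545 to 108168956), had 0 counts in uninduced cells and 12.2 ± 0.108 CPM in induced cells, at least 886-fold higher (adjusted p = 6.17e-12). The ligands IHH (chromosome 2, 219054420 to 219060467) and SHH (chromosome 7, 155799986 to 155812273) of the hedgehog family rose by 9.14 ± 0.22 and 7.95 ± 0.36 on the log2 scale, to 13.8 ± 0.992 and 6.03 ± 0.123 CPM. The cartilage matrix protein COMP (chromosome 19, 18782773 to 18791314) rose by 7.78 ± 0.19, from 0.386 ± 0.0643 to 85.1 ± 13.3 CPM (adjusted p = 6.16e-11). NGFR, a neurotrophin receptor (chromosome 17, 49495293 to 49515017), rose from 3 counts to 53.9 ± 0.253 CPM, a ratio of 3901 (interval 1334 to 18919; adjusted p = 6.25e-18).

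NDNF, a secreted neurotrophic factor, was also among the highest (15.6 CPM induced, 2 uninduced counts, ratio 1695, interval 469 to 14006). NXPH2, a secreted neurexin ligand (7.74 CPM, 1 uninduced count, ratio 1679, interval 301 to 66376) and NEFL, the neurofilament light chain (8.48 CPM, 2 uninduced counts, ratio 921, interval 254 to 7609) followed. RASD1, a Ras-like GTPase, rose by 8.30 ± 0.20 and PGM5, a phosphoglucomutase relative of cell junctions, by 8.12 ± 0.18 on the log2 scale. Among these 10 genes, adjusted p lay between 6.25e-18 for NGFR and 3.74e-10 for SHH. Exons of LEF1, NGFR, NEFL and PGM5 overlap those of annotated non-coding genes, mostly on the opposite strand. The lowest changes belonged to SLC7A14, a solute carrier (-3.11 ± 0.08, from 15.8 to 1.83 CPM), GPRC5A, a receptor induced by retinoic acid (-2.88 ± 0.07, 87.1 to 11.8 CPM), and GDF5, a growth factor of joint formation (-2.69 ± 0.07, 75.4 to 11.6 CPM). TMEM40 (-2.64 ± 0.06) and LMOD1, an actin nucleator of smooth muscle (-2.48 ± 0.06, 89.3 to 16.1 CPM), came next. They were followed by DEPP1 (-2.43 ± 0.07), MGAM, a starch-digesting glucosidase (-2.38 ± 0.13), JPH2, a junction protein of muscle membranes (-2.25 ± 0.13), MGARP, a mitochondrial protein (-2.19 ± 0.05, 146 to 32.0 CPM), and ADAMTS5, an aggrecan-cleaving protease (-2.19 ± 0.09, 39.1 to 8.60 CPM). Their adjusted p lay between 6.75e-17 for MGARP and 6.52e-11 for JPH2. GDF5 overlaps the antisense gene GDF5OS, while DEPP1, MGAM, LMOD1 and SLC7A14 overlap RASSF4, CLEC5A, AL513217.1 and AC026316.4 or AC026316.5 on the opposite strand, and MGARP shares 360 exon bases with NDUFC1 on its own strand.

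Of the genes fixed in advance, PDGFB, a mitogen of mesenchymal cells (ENSG00000100311.16, chromosome 22, 39223359 to 39244751), rose from 0.171 ± 0.0387 to 18.4 ± 0.0683 CPM (log2 change 6.74 ± 0.18, adjusted p = 1.15e-15). Its receptors rose by less, PDGFRA by 1.90 ± 0.05 (chromosome 4, 54229097 to 54298247; adjusted p = 1.99e-15) and PDGFRB by 0.51 ± 0.04 (adjusted p = 1.16e-08); PDGFRA shares 1533 exon bases with AC058822.1. BCL2, which blocks apoptosis (chromosome 18, 63123346 to 63320128), rose from 0.276 ± 0.00309 to 2.60 ± 0.608 CPM (3.22 ± 0.28, adjusted p = 2.3e-08). HES1, a Notch-induced repressor (chromosome 3, 194136145 to 194138732), rose from 0.485 ± 0.0891 to 21.8 ± 1.61 CPM (5.49 ± 0.15, adjusted p = 1.29e-15). NRARP, a feedback inhibitor of Notch, rose by 1.94 ± 0.26 (adjusted p = 6.47e-06). HEYL had 3 uninduced counts and a ratio of 31.8 (interval 10.5 to 157, adjusted p = 2.28e-05). CCND1, which drives entry into S phase (chromosome 11, 69641087 to 69654474; 497 exon bases opposite LTO1), rose from 558 ± 15.7 to 2267 ± 5.61 CPM (2.02 ± 0.07, adjusted p = 7.12e-13). CDKN1A, a cell cycle inhibitor, fell by 0.28 ± 0.04 (adjusted p = 2.76e-05). Among transcription factors, SOX4 rose by 1.37 ± 0.08, the osteoblast factor RUNX2 by 0.60 ± 0.06 and MYC by 0.35 ± 0.05 (adjusted p = 5.5e-10, 1.8e-07 and 4.26e-06). The cartilage factor SOX9 changed by 0.22 ± 0.09 (adjusted p = 0.0447), HES4 by -0.10 (adjusted p = 0.794) and PDGFA by -0.11 (adjusted p = 0.215). HEY2 and the cartilage genes COL2A1 and ACAN had too few counts to be tested.

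**Figure D2:**
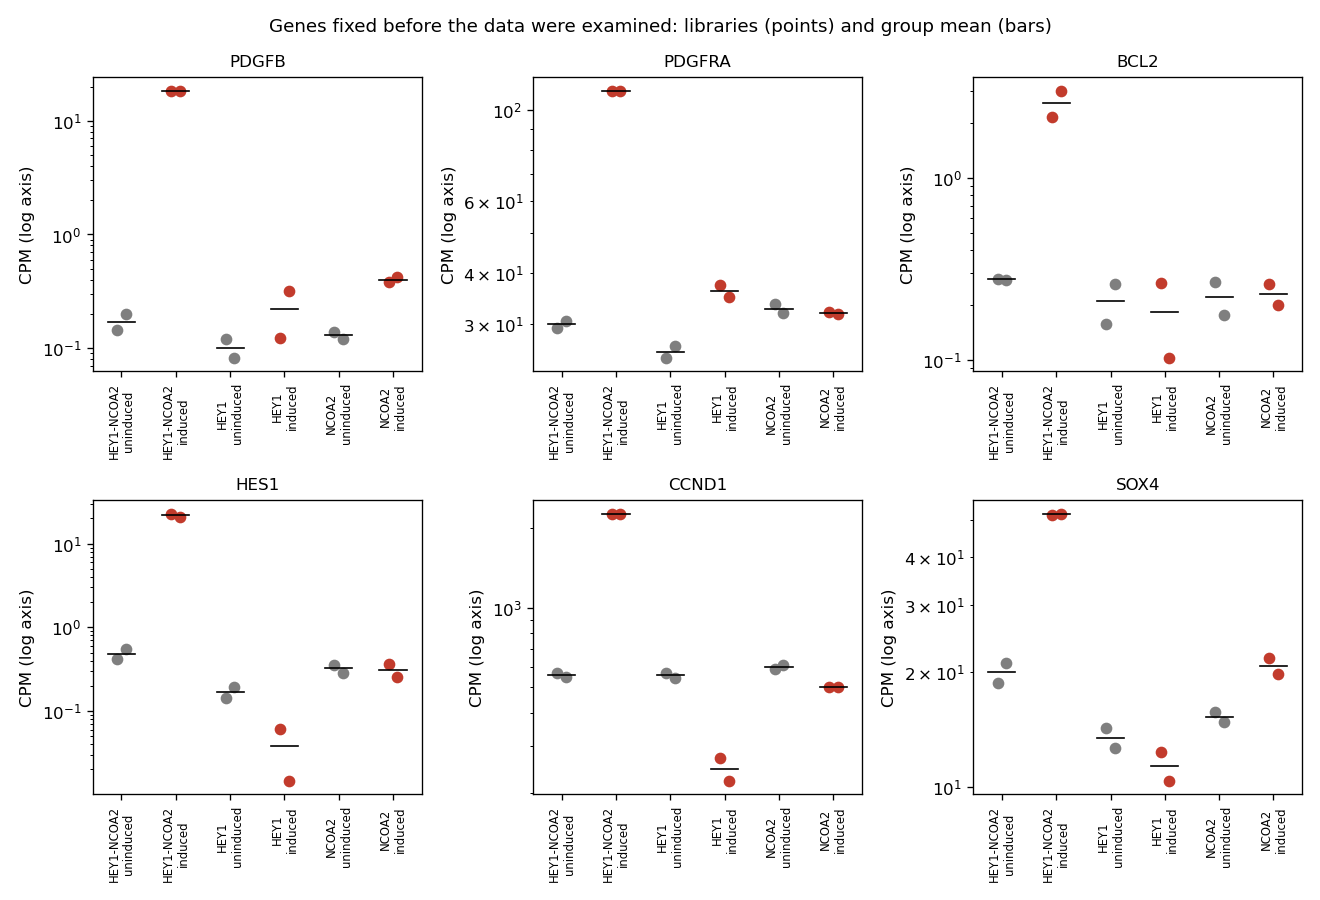
Levels of 6 of the genes fixed in advance (PDGFB, PDGFRA, BCL2, HES1, CCND1, SOX4) in each library, in CPM on log axes, by line and induction; points are libraries and bars the mean of the 2 libraries of a group. CCND1 stood at 2267 CPM in the induced fusion line and at 246 CPM in the induced HEY1 line.

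Genes of cell division rose together with the fusion. Of 40 measured members of the mitosis list, 38 rose and 2 did not pass (38 rose adjusted over the list alone), with a median log2 change of 0.68. AURKA, a spindle kinase, rose by 3.31 ± 0.07, the securin PTTG1 by 1.47 ± 0.06, CKAP2 by 1.11 ± 0.06 and the motor KIF11 by 1.07 ± 0.06. The list passed camera (adjusted p = 2.95e-10), with adjusted p = 0.112 with an estimated correlation. Of 33 members of the DNA replication list, 31 rose and 2 did not pass (31 rose adjusted over the list alone; median 0.75), among them RRM2 (1.27 ± 0.07), which makes deoxynucleotides, the flap nuclease FEN1 (0.78 ± 0.06) and the helicase subunits MCM7 (0.89 ± 0.06) and MCM4 (0.89 ± 0.07). Camera gave adjusted p = 8.33e-07 for replication, and adjusted p = 0.106 with an estimated correlation. Targets of p53 moved the other way: 15 of 29 fell, 5 rose and 9 did not pass (15 and 5 adjusted over the list alone; median -0.23). The p53 list had camera adjusted p = 0.0228, and adjusted p = 0.117 with an estimated correlation. PLK2 (-0.86 ± 0.05), GADD45A (-1.05 ± 0.06), TNFRSF10C (-1.13 ± 0.08) and SPATA18 (-0.99 ± 0.09) fell, whereas PMAIP1 (1.24 ± 0.11), XPC (0.34 ± 0.05), TP53INP1, PLK3 and TP53I3 rose.

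Several signalling lists rose with the fusion. In the Notch list, 15 of 27 members rose, 5 fell and 7 did not pass (15 and 5 adjusted over the list alone; median 1.01). HES1, HES2 (5.95 ± 0.25), HES6 (2.90 ± 0.17) and the glycosyltransferase LFNG (1.12 ± 0.06) rose, and NUMBL (-0.52 ± 0.07), NOTCH2 (-0.49 ± 0.06), MAML2, RFNG and NUMB fell. Camera gave adjusted p = 0.000123, and adjusted p = 0.121 with an estimated correlation. In the hedgehog list, 9 of 13 rose, 3 fell and 1 did not pass (9 and 3 adjusted over the list alone; median 1.15). For the hedgehog list camera gave adjusted p = 8.33e-07, and adjusted p = 0.106 with an estimated correlation. The receptor and target PTCH1 (3.36 ± 0.09), the inhibitor HHIP (2.55 ± 0.15), IHH and SHH rose, and GLI3 (-0.42 ± 0.08), SMO (-0.29 ± 0.06) and SUFU (-0.16 ± 0.06) fell. All 14 measured Wnt targets changed, 12 higher and 2 lower (12 and 2 adjusted over the list alone; median 1.46). The Wnt target list had camera adjusted p = 3.76e-05, and adjusted p = 0.0919 with an estimated correlation. The feedback inhibitors NKD1 (6.90 ± 0.28) and AXIN2 (3.30 ± 0.19) rose with LEF1, and the secreted inhibitors DKK1 (-1.0 ± 0.05) and DKK2 (-0.70 ± 0.16) fell. Of 6 PDGF ligands and receptors, 4 rose, 1 fell and 1 did not pass (4 and 1 adjusted over the list alone; median 0.56), PDGFC rising by 0.61 ± 0.05 and PDGFRL falling (-1.66 ± 0.06). For the PDGF list camera gave adjusted p = 0.000221, and adjusted p = 0.101 with an estimated correlation.

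Feedback genes of FGF and ERK signalling rose in 14 of 18 cases, with 1 lower and 3 not passing (14 and 1 adjusted over the list alone; median 0.66), among them SPRED2 (2.21 ± 0.07), ETV4 (2.79 ± 0.10) and the ERK phosphatase DUSP6 (1.2 ± 0.07), while IER3 fell (-0.57 ± 0.04). Camera gave adjusted p = 1.08e-07, and adjusted p = 0.117 with an estimated correlation. Of 15 BMP targets, 11 rose, 3 fell and 1 did not pass (11 and 3 adjusted over the list alone; median 1.59). The BMP target list had camera adjusted p = 0.0135, and adjusted p = 0.163 with an estimated correlation. ID4 (3.28 ± 0.20) and SMAD6 (1.69 ± 0.10) rose, and the antagonists BAMBI (-0.97 ± 0.05) and GREM1 (-1.10 ± 0.06) fell with SMAD9 (-0.47 ± 0.12). Of 17 TGF-beta targets, 9 rose, 6 fell and 2 did not pass (10 and 6 adjusted over the list alone; median 0.29). For the TGF-beta list camera gave adjusted p = 0.0092, and adjusted p = 0.383 with an estimated correlation. LRRC15 (5.80 ± 0.13), PMEPA1 (1.68 ± 0.07), BHLHE40 (1.25 ± 0.05) and LMCD1 (1.44 ± 0.07) rose, and TNS1 (-0.76 ± 0.05), CCN2 (-0.72 ± 0.09), TGFBR1, SKIL and LTBP2 fell.

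The cartilage and bone lists passed as higher with the fusion, and the smooth muscle and epithelial lists as lower. Of 17 measured cartilage genes, 8 rose, 2 fell and 7 did not pass (9 and 2 adjusted over the list alone; median 0.30). The cartilage list had camera adjusted p = 9.6e-05, and adjusted p = 0.0919 with an estimated correlation. The matrilins MATN3 (5.46 ± 0.08) and MATN2 (0.62 ± 0.05), COMP and CYTL1 (0.69 ± 0.05) rose, and COL11A2 (-0.94 ± 0.27) and WWP2 (-0.15 ± 0.06) fell. Of 15 bone genes, 9 rose, 4 fell and 2 did not pass (9 and 4 adjusted over the list alone; median 1.39). For the bone list camera gave adjusted p = 0.00188, and adjusted p = 0.126 with an estimated correlation. The osteocyte inhibitor of Wnt signalling SOST (6.99 ± 0.16) and the parathyroid hormone receptor PTH1R (4.40 ± 0.18) rose, and TNFRSF11B (-0.78 ± 0.05), COL1A2 (-0.72 ± 0.06), SPARC (-0.47 ± 0.05) and COL1A1 (-0.40 ± 0.07) fell. In the smooth muscle list 16 of 20 fell, 1 rose and 3 did not pass (16 and 1 adjusted over the list alone; median -0.38). The smooth muscle list had camera adjusted p = 3.6e-08, and adjusted p = 0.106 with an estimated correlation. LMOD1, CNN1 (-1.55 ± 0.05) and the actin ACTA2 (-0.99 ± 0.06) fell, and DES rose (1.08 ± 0.35). Of 14 epithelial genes 8 fell and 6 did not pass (8 fell adjusted over the list alone; median -0.45), among them the keratins KRT18 (-1.21 ± 0.05), KRT7 (-1.13 ± 0.06) and KRT8 (-0.46 ± 0.05) and the mucin MUC1 (-0.75 ± 0.10). For the epithelial list camera gave adjusted p = 0.00519, and adjusted p = 0.106 with an estimated correlation. In the list of heart and mesoderm transcription factors 7 of 12 rose, 2 fell and 3 did not pass (7 and 2 adjusted over the list alone; median 0.79, and 0.39 on the TPM scale), with camera adjusted p = 0.0235, and adjusted p = 0.501 with an estimated correlation. In the neural list 3 of 7 rose and 4 did not pass (3 rose adjusted over the list alone; median 0.53, and 0.26 on the TPM scale), with camera adjusted p = 0.00536, and adjusted p = 0.106 with an estimated correlation. The skeletal muscle list did not pass camera (3 of 8 higher, 1 lower and 4 not passing, 3 and 1 adjusted over the list alone; median 0.45, adjusted p = 0.427).

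The lists of hypoxia and glycolysis, of the integrated stress response and of YAP targets fell with the fusion. Of 31 genes of hypoxia and glycolysis, 24 fell, 4 rose and 3 did not pass (24 and 5 adjusted over the list alone; median -0.43). The hypoxia list had camera adjusted p = 2.18e-05, and adjusted p = 0.106 with an estimated correlation. PFKFB4 (-1.21 ± 0.05), BNIP3 (-0.85 ± 0.05) and CA9 (-1.43 ± 0.08) fell, and NDRG1 (2.71 ± 0.05), PFKFB3, ANKRD37 and EGLN3 rose. Of 31 genes of the integrated stress response, 24 fell, 4 rose and 3 did not pass (26 and 4 adjusted over the list alone; median -0.28). For the stress response list camera gave adjusted p = 0.000979, and adjusted p = 0.249 with an estimated correlation. DDIT4 (-1.09 ± 0.06) and TRIB3 (-0.79 ± 0.05) fell, and the subunits SLC7A5 (1.17 ± 0.07) and SLC3A2 (0.68 ± 0.05) of an amino acid transporter, WARS and PHGDH rose. Of 21 YAP targets, 15 fell, 2 rose and 4 did not pass (15 and 3 adjusted over the list alone; median -0.43), with ANKRD1 (-1.46 ± 0.05), GADD45A, LATS2 (-0.78 ± 0.05) and CRIM1 (-0.82 ± 0.06) lower and AMOTL1 (0.15 ± 0.05) and TEAD1 (0.14 ± 0.05) higher. The YAP target list had camera adjusted p = 2.18e-05, and adjusted p = 0.329 with an estimated correlation. The heat shock, unfolded protein and cholesterol lists did not pass camera. In the heat shock list 9 of 15 rose and 4 fell (9 and 5 adjusted over the list alone; median 0.21, adjusted p = 0.27), and in the list of the unfolded protein response 8 of 18 rose and 2 fell (8 and 2 adjusted over the list alone; median 0.10, adjusted p = 0.39). In the cholesterol list 10 of 25 fell and 5 rose (10 and 5 adjusted over the list alone; median -0.12, and 0.01 on the TPM scale; adjusted p = 0.192). The glucocorticoid target list passed as higher (7 of 15 rose, 3 fell and 5 did not pass; 7 and 4 adjusted over the list alone) although its median was -0.04, with camera adjusted p = 0.0228, and adjusted p = 0.383 with an estimated correlation.

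**Figure D3:**
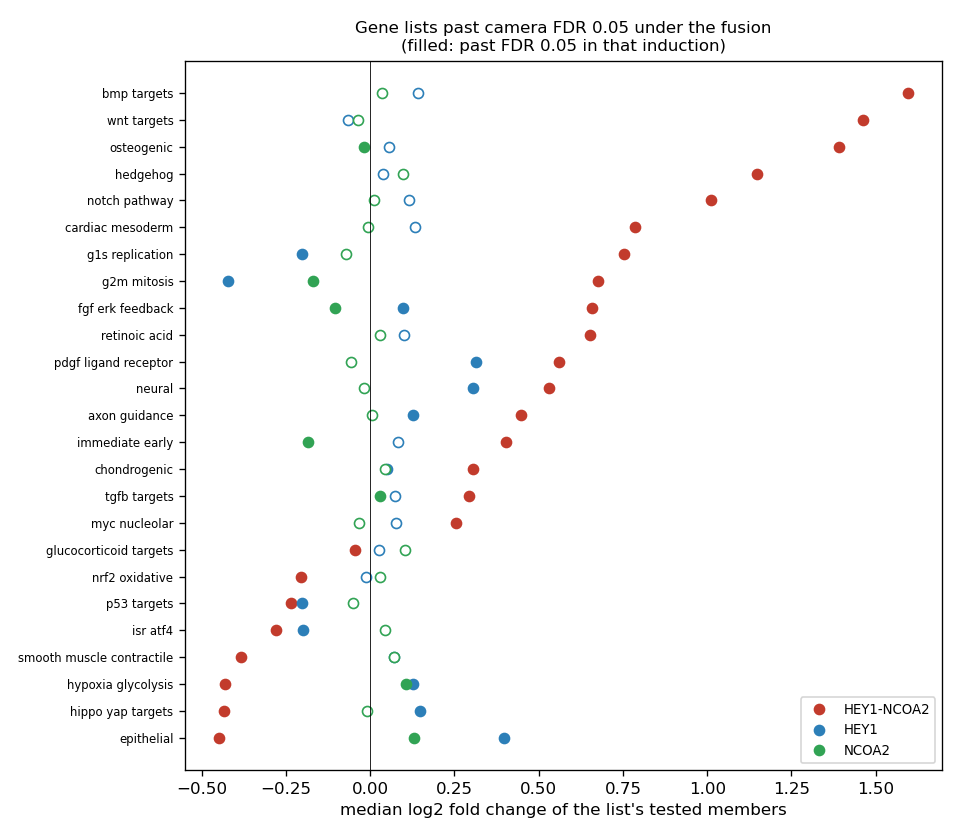
Median log2 change (horizontal axis) of the tested members of the 25 lists (vertical axis) that passed camera with the fusion, for the 3 inductions; a filled point passed in that induction. The mitosis list stood at 0.68 with the fusion and -0.42 with HEY1. The glucocorticoid median of -0.04 with the fusion became 0.07 on the TPM scale, and several medians between -0.07 and 0.10 with HEY1 or NCOA2 also changed sign there. The neural median of 0.31 with HEY1 was 0.08 with low-count members at their bound.

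Over all genes, 4649 rose and 4380 fell with the fusion, 49.7% of those tested; 1647 rose and 686 fell by more than 2-fold, and 536 rose and 25 fell by more than 8-fold. Of the 50 lists, 18 passed camera as higher and 7 as lower. With an estimated correlation 0 did so, and 12 were higher and 4 lower at an unadjusted p under 0.05. On the TPM scale with a pseudocount of 1 the number of lower genes was 2355, the share of higher genes 64.6% instead of 51.5%. There the medians of the Notch, Wnt, BMP, bone, cartilage, p53, YAP and epithelial lists were 0.23, 0.53, 0.85, 0.60, 0.13, -0.10, -0.17 and -0.25. Calls ended for SOX9, LTBP2, WWP2 and TEAD1 in at least 9 settings (SOX9 at adjusted p = 0.402 without induced replicate 2 of the line), for SMO, MAML2, NUMB and SKIL on the TPM scale, and for RFNG, SUFU and SMAD9 there or without 1 library of the line. Those for AMOTL1, COL11A2, DES, EGLN3, PHGDH, PLK3, TP53I3 and TP53INP1 ended without at least 1 library of the line, at adjusted p from 0.0540 for COL11A2 without uninduced replicate 1 to 0.255 for AMOTL1 without uninduced replicate 2.

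Induction of HEY1, the comparator that the series design names, changed fewer genes than the fusion, 32 of 40 mitosis genes among those lowered (camera adjusted p = 6.73e-17, and adjusted p = 0.115 with an estimated correlation). SERPINB2, an inhibitor of plasminogen activators, rose by 2.76 ± 0.15 on the log2 scale, from 25.7 ± 4.52 to 175 ± 15.4 CPM (adjusted p = 1.89e-05; 547 exon bases shared with SERPINB10). The semaphorin SEMA3B (chromosome 3, 50267558 to 50277546) rose by 2.54 ± 0.09 (3.74 to 21.8 CPM, adjusted p = 3.19e-12) and ANGPTL4, an inhibitor of lipoprotein lipase, by 2.26 ± 0.15. IGFBP3, a carrier of insulin-like growth factors, rose by 1.83 ± 0.05 (466 to 1661 CPM, adjusted p = 2.94e-14). CYP1B1, a cytochrome P450 (chromosome 2, 38066973 to 38109902; exons opposite CYP1B1-AS1), was lowest, at -2.23 ± 0.07 (36.8 to 7.85 CPM, adjusted p = 6.28e-13), followed by the collagen cross-linking enzyme LOXL4 (-2.11 ± 0.07, 19.7 to 4.56 CPM). CCND1 fell from 555 ± 14.6 to 246 ± 34.8 CPM (-1.17 ± 0.07, adjusted p = 1.28e-08).

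Further genes with the highest changes were TINAGL1 (2.11 ± 0.13), RAB7B, a small GTPase (1.93 ± 0.14), KISS1 (1.55 ± 0.20), NPTX1, a neuronal pentraxin (1.48 ± 0.10), and F3, the trigger of coagulation (1.43 ± 0.09). Besides HEY1 itself, adjusted p of the highest genes lay between 2.94e-14 for IGFBP3 and 4.25e-05 for KISS1. PLPP4 (-1.78 ± 0.10), the metallothionein MT2A (-1.62 ± 0.06, 153 to 49.8 CPM), SH3TC1 (-1.57 ± 0.13), P2RX6, an ATP-gated channel (-1.49 ± 0.13), LPCAT2 (-1.37 ± 0.05), C15orf48 (-1.26 ± 0.08) and GNPDA1 (-1.14 ± 0.06) fell. Adjusted p of the lowest genes lay between 3.79e-13 for LOXL4 and 3.99e-07 for P2RX6. Among genes fixed in advance, SOX9 rose by 0.64 ± 0.09 (adjusted p = 6.98e-05), PDGFRA by 0.49 ± 0.05 (adjusted p = 5.07e-06) and MYC by 0.21 ± 0.05 (adjusted p = 0.00628). CDKN1A fell by 0.45 ± 0.04 (adjusted p = 1.18e-06), RUNX2 by 0.21 ± 0.07 (adjusted p = 0.0411) and HES1 by 2.11 ± 0.57 (adjusted p = 0.0178), the last with 5 counts in the induced libraries, 0.0381 CPM against 0.170. PDGFB changed by 1.1 (adjusted p = 0.093), SOX4 by -0.25 (adjusted p = 0.0798) and BCL2 by -0.17 (adjusted p = 0.859).

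Of 40 mitosis genes, 32 fell with HEY1 and 8 did not pass (36 fell adjusted over the list alone; median -0.42), among them the topoisomerase TOP2A (-0.56 ± 0.06), PTTG1 (-0.54 ± 0.07), KIF11 (-0.56 ± 0.07) and NUSAP1 (-0.72 ± 0.09). Their camera call ended with an estimated correlation (adjusted p = 0.115). Of 33 replication genes 11 fell and 22 did not pass (13 fell adjusted over the list alone; median -0.20), such as RRM2 (-0.42 ± 0.08), RFC2 (-0.31 ± 0.08) and CDC45 (-0.59 ± 0.14). The replication list had camera adjusted p = 0.000311, and adjusted p = 0.194 with an estimated correlation. Of 31 genes of the integrated stress response 17 fell and 14 did not pass (19 fell adjusted over the list alone; median -0.20). For the stress response list camera gave adjusted p = 8.64e-15, and adjusted p = 0.0863 with an estimated correlation. PSAT1 (-0.78 ± 0.05), which makes serine, SLC3A2 (-0.70 ± 0.05), SLC7A5 (-0.99 ± 0.07) and the asparagine synthetase ASNS (-0.75 ± 0.06) fell. Of 29 p53 targets 16 fell, 3 rose and 10 did not pass (21 and 4 adjusted over the list alone; median -0.20). The p53 list had camera adjusted p = 9.14e-08, and its call held with an estimated correlation (adjusted p = 0.0191). CDKN1A, TP53INP1 (-0.59 ± 0.06), SESN1 (-0.53 ± 0.06) and RRM2B (-0.47 ± 0.05) fell, and GADD45A (0.34 ± 0.06), TP53I3 (0.32 ± 0.06) and TNFRSF10C (0.33 ± 0.08) rose.

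Epithelial, hypoxia and YAP target lists rose with HEY1. Of 14 epithelial genes 6 rose and 8 did not pass (6 rose adjusted over the list alone; median 0.40). The epithelial list had camera adjusted p = 6.24e-08, and its call held with an estimated correlation (adjusted p = 0.0191). KRT7 rose by 1.0 ± 0.06, KRT19 by 0.71 ± 0.06, KRT18 by 0.43 ± 0.04 and the junction protein OCLN by 0.68 ± 0.10. Of 31 hypoxia genes 14 rose, 4 fell and 13 did not pass (16 and 4 adjusted over the list alone; median 0.13). The hypoxia list had camera adjusted p = 2.68e-05, and adjusted p = 0.18 with an estimated correlation. HK2 (0.70 ± 0.05), ALDOC (0.53 ± 0.05), SLC2A3 (0.41 ± 0.05) and NDRG1 (0.35 ± 0.05) rose, and VEGFA (-0.20 ± 0.04), ALDOA, ENO2 and PDK1 fell. Of 21 YAP targets 9 rose, 4 fell and 8 did not pass (10 and 4 adjusted over the list alone; median 0.15), with IGFBP3, F3 and ANKRD1 (0.75 ± 0.05) higher and ARHGEF17 (-0.45 ± 0.05), AXL (-0.41 ± 0.06), AJUBA and ASAP1 lower. For the YAP target list camera gave adjusted p = 1.3e-07, and adjusted p = 0.29 with an estimated correlation. In the Notch list 2 of 27 rose, 4 fell and 21 did not pass (2 and 4 adjusted over the list alone), and the list did not pass camera (median 0.11, adjusted p = 0.736). RBPJ, the DNA-binding partner of Notch, fell (-0.83 ± 0.06) with HES6 (-0.87 ± 0.24), LFNG (-0.24 ± 0.07) and HES1, and NOTCH3 (0.49 ± 0.10) and the ligand DLL1 (1.43 ± 0.39) rose.

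With HEY1, 1376 genes rose and 1397 fell, 15.3% of those tested; 206 rose and 116 fell by more than 2-fold. Of the 50 lists 14 passed camera as higher and 4 as lower, 1 in each direction with an estimated correlation. The higher lists without examples here were those of axon guidance (median 0.13), basement membrane (0.13), cartilage (0.05), cytoplasmic ribosomal proteins (0.11), FGF and ERK feedback (0.10), fibrillar matrix (0.06), heat shock (0.06), stromal cell identity (0.10), neural genes (0.31, and 0.08 with low-count members at their bound) and PDGF ligands and receptors (0.31). Their camera adjusted p lay between 6.75e-05 and 0.0462, and their adjusted p with an estimated correlation between 0.18 and 0.727. The counts were 834 and 824 without uninduced replicate 1 of the HEY1 line, 876 higher without uninduced replicate 2, 860 and 764 with the 4 libraries of the line alone, and 530 and 1056 on the TPM scale with a pseudocount of 1. There the medians of the epithelial, YAP and hypoxia lists were 0.16, 0.08 and 0.06, and those of the 10 lists without examples 0.01 to 0.17. Calls ended for HES1 on that TPM scale or without uninduced or induced replicate 2 of the line (adjusted p = 0.0908 and 0.168), for MYC on both TPM scales or without uninduced replicate 2 (adjusted p = 0.0784), for RUNX2 in 13 settings and for VEGFA with the 4 libraries alone. Those for DLL1, HES6, LFNG, NOTCH3, ASAP1, CDC45, RFC2, TNFRSF10C, ALDOA, ENO2 and PDK1 ended without at least 1 library of the line, at adjusted p from 0.0538 for ENO2 without uninduced replicate 2 to 0.302 for HES6 without uninduced replicate 1.

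Induction of NCOA2, the other fusion partner, raised genes of sterol synthesis. It changed 969 genes against 2773 with HEY1, but with only the libraries of each line the order turned, 2447 against 1624. ABCA1, the pump that moves cholesterol out of cells, rose by 1.72 ± 0.08 on the log2 scale, from 3.93 ± 0.245 to 13 ± 0.172 CPM (adjusted p = 6.43e-10). TNFRSF11B, the decoy receptor osteoprotegerin, rose by 1.58 ± 0.05 (27.4 to 81.8 CPM, adjusted p = 1.85e-12), MGP, an inhibitor of calcification, by 1.63 ± 0.09 (6.23 to 19.3 CPM), and DHRS3, a retinaldehyde reductase, by 1.45 ± 0.08. MELTF (1.66 ± 0.10), the secretory kinase FAM20C (1.26 ± 0.10, 38.0 to 91.3 CPM), CLSTN2 (1.25 ± 0.06), the sulfotransferase SULT1B1 (1.2 ± 0.13) and PRSS35 (1.05 ± 0.07) followed. Besides NCOA2 itself, adjusted p of the highest genes reached from 1.85e-12 for TNFRSF11B to 3.26e-05 for FAM20C. The lowest changes were those of EPGN, a ligand of the EGF receptor (-1.03 ± 0.09), ADAMTS14 (-0.98 ± 0.06), the immunoproteasome subunit PSMB9 (-0.77 ± 0.10), and the channel KCNN3 (-0.75 ± 0.11). They included the protease urokinase PLAU (-0.74 ± 0.05, 667 to 400.5 CPM; opposite C10orf55), GDF5 (-0.73 ± 0.06) and the adhesion molecule VCAM1 (-0.72 ± 0.09, 180.4 to 110 CPM). ARVCF (-0.69 ± 0.11), LRRC17 (-0.66 ± 0.05; opposite FBXL13) and CD83 (-0.61 ± 0.08) completed the 10. Adjusted p lay between 5.94e-09 for ADAMTS14 and 0.000696 for ARVCF.

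Among genes fixed in advance, PDGFB rose with NCOA2 by 1.61 ± 0.31 (0.130 to 0.401 CPM, adjusted p = 0.00369), and SOX4 by 0.45 ± 0.08 (adjusted p = 0.00345). RUNX2 rose by 0.39 ± 0.06 (adjusted p = 0.000494) and PDGFRB by 0.24 ± 0.04 (adjusted p = 0.00167), and CCND1 fell by 0.26 ± 0.07 (adjusted p = 0.037). HES1 (-0.03), BCL2 (0.07), SOX9 (-0.11), CDKN1A (0.05), MYC (0.10) and PDGFRA (-0.03) did not pass. Of 25 genes of cholesterol synthesis and uptake 17 rose and 8 did not pass (22 rose adjusted over the list alone; median 0.29). The cholesterol list had camera adjusted p = 3.18e-24, and its call held with an estimated correlation (adjusted p = 0.0185). The sensor INSIG1 rose by 0.46 ± 0.06 and the enzyme CYP51A1 by 0.37 ± 0.05. Of 14 epithelial genes 5 rose and 9 did not pass (5 rose adjusted over the list alone; median 0.13). The epithelial list had camera adjusted p = 5.61e-06, and its call held with an estimated correlation (adjusted p = 0.0451). KRT7 (0.65 ± 0.06), KRT19 (0.57 ± 0.06), KRT18 (0.37 ± 0.04) and KRT8 (0.30 ± 0.05) rose. Of 31 hypoxia genes 9 rose and 22 did not pass (14 rose adjusted over the list alone; median 0.11), such as ADM (0.39 ± 0.06), NDRG1 (0.30 ± 0.05), PFKFB4 and SLC2A3 (0.28 ± 0.05 each). The hypoxia list had camera adjusted p = 1.92e-07, and adjusted p = 0.128 with an estimated correlation.

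Inflammatory lists fell with NCOA2. Of 24 NF-kappaB target genes 9 fell, 2 rose and 13 did not pass (10 and 2 adjusted over the list alone; median -0.14). For the NF-kappaB list camera gave adjusted p = 4.8e-06, and adjusted p = 0.542 with an estimated correlation. The cytokines LIF (-0.56 ± 0.04), CCL2 (-0.50 ± 0.05) and IL1A (-0.54 ± 0.08) fell, and SOD2 (0.32 ± 0.05) and BIRC3 (0.31 ± 0.07) rose. Of 23 interferon response genes 6 fell and 17 did not pass (9 fell adjusted over the list alone; median -0.14), among them IFIT3 (-0.47 ± 0.08), DDX58 (-0.29 ± 0.07), ISG15 (-0.37 ± 0.09) and IFI44 (-0.57 ± 0.14). The interferon list had camera adjusted p = 0.00212, and adjusted p = 0.243 with an estimated correlation. The bone list passed as higher (3 of 15 rose, 0 fell and 12 did not pass; 3 higher and 1 lower adjusted over the list alone), with TNFRSF11B, RUNX2 and SOST (2.22 ± 0.35) higher. Its mean was 0.20 while its median was -0.02, and 0.02 on the TPM scale. For the bone list camera gave adjusted p = 0.000102, and adjusted p = 0.183 with an estimated correlation. Of the 13 mRNAs of the mitochondrial genome 1, MT-ND1 (-0.28 ± 0.05), fell and 12 did not pass (8 fell adjusted over the list alone; median -0.18). The mitochondrial list had camera adjusted p = 5.61e-06, and adjusted p = 0.542 with an estimated correlation. The mitosis list, lower with HEY1, passed as lower with NCOA2 too (2 of 40 fell and 38 did not pass; 5 fell adjusted over the list alone; median -0.17), with camera adjusted p = 5.61e-06, and adjusted p = 0.394 with an estimated correlation.

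With NCOA2, 562 genes rose and 407 fell, 5.33% of those tested; 52 rose and 15 fell by more than 2-fold. Of the 50 lists, 6 passed camera as higher and 9 as lower, 2 as higher and 0 as lower with an estimated correlation (4 and 2 at an unadjusted p under 0.05). Among lists without examples here, those of TGF-beta targets (median 0.03) and PI3K signalling (0.06) were higher, and those of cytoplasmic ribosomal proteins (-0.06), FGF and ERK feedback (-0.11), heat shock (-0.09) and matrix proteases (-0.08) lower. Their camera adjusted p lay between 0.00175 and 0.0331, and their adjusted p with an estimated correlation between 0.234 and 0.709. The counts of 562 and 407 genes fell whichever of the line's 4 libraries was left out. Each removal leaves 1 library in a group, so the fall does not show that any library drove the calls. The counts were 246 and 118 on the TPM scale with a pseudocount of 1, and 1376 and 1071 with these 4 libraries alone. The TPM medians of the epithelial, interferon, FGF and ERK, protease and ribosomal lists were 0.04, -0.07, -0.06, -0.05 and -0.02. Calls that ended were those of SULT1B1 and KCNN3 on the TPM scale, PDGFB, SOX4 and PDGFRB on the TPM scale or without uninduced replicate 2 (adjusted p = 0.0654, 0.0690 and 0.0534), SOX4 also without induced replicate 1 (adjusted p = 0.0649), CCND1 in 9 settings, and SOST and RUNX2 on 1 of the TPM scales. Those for BIRC3, DDX58, ISG15, IFI44, MT-ND1 and SLC2A3 ended without at least 1 library of the line, at adjusted p from 0.0504 for MT-ND1 without uninduced replicate 1 to 0.217 for BIRC3 without induced replicate 2.

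The series design asks how targets of the fusion compare with those of HEY1, so the difference of the 2 induction effects was tested for each gene. CCND1 rose with the fusion and fell with HEY1, a log2 difference of 3.20 ± 0.10 (adjusted p = 4.47e-13), and so did LOXL4 (4.79 ± 0.07 against -2.11 ± 0.07), which was singled out in this direction after its values were seen. HES1 differed by 7.60 ± 0.59 (adjusted p = 7.97e-09), and PDGFB by 5.64 ± 0.61 (adjusted p = 6.57e-07). BCL2 differed by 3.39 ± 0.55 (adjusted p = 6.63e-05), SOX4 by 1.62 ± 0.12 (adjusted p = 2.02e-08) and PDGFRA by 1.41 ± 0.07 (adjusted p = 4.87e-11). Differences of NRARP (1.62 ± 0.44), RUNX2 (0.81 ± 0.09) and PDGFRB (0.48 ± 0.06) also passed (adjusted p = 0.00605, 9.08e-07 and 4.37e-06), and SOX9 differed by -0.43 ± 0.12 (adjusted p = 0.0102) and CDKN1A by 0.17 ± 0.06 (adjusted p = 0.0389). MYC (0.15, adjusted p = 0.085) and PDGFA (-0.25, adjusted p = 0.066) did not pass.

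The highest differences were those of genes that the fusion raised from low levels. COMP differed by 8.71 ± 0.61 (85.1 CPM in induced fusion cells, 0.203 in induced HEY1 cells) and RGCC, a regulator of the cell cycle, by 8.35 ± 0.50 (51.3 and 0.113 CPM). The monocarboxylate transporter SLC16A6 differed by 8.09 ± 0.42 (161.7 and 0.0903 CPM), PGM5 by 8.58 ± 0.81, and TH, which makes the precursor of dopamine, by 8.33 ± 0.66. For LRATD1, NGFR, NDNF, NEFL and TRIM67 at most 3 counts lay behind 1 group or more. They stood at 25.9, 53.9, 15.6, 8.48 and 26.9 CPM in induced fusion cells. In induced HEY1 cells LRATD1 had 0 counts and the others stood at 0.0912, 0.0223, 0.0308 and 0.0218 CPM. Adjusted p of these 10 lay between 4.14e-11 for SLC16A6 and 9.25e-05 for NEFL. The lowest differences were those of RAB7B (-4.78 ± 0.23), SEMA3B (-3.91 ± 0.14), SLC7A14 (-3.84 ± 0.11), TINAGL1 (-3.65 ± 0.18), and GPRC5A (-3.62 ± 0.09). TENT5B, a poly(A) polymerase (-3.32 ± 0.15), TMEM40 (-3.16 ± 0.08), the kinase NIM1K (-3.05 ± 0.21), MGAM (-2.99 ± 0.16) and JPH2 (-2.94 ± 0.18) followed, with adjusted p between 2.05e-15 for GPRC5A and 1.29e-09 for NIM1K.

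Genes of cell division had the smallest camera p among the lists. The Wnt target and bone lists, with medians of 1.89 and 1.76, and 0.70 each on the TPM scale, did not pass (adjusted p = 0.299 and 0.32). Of 40 mitosis genes 38 were higher and 2 did not pass (38 higher adjusted over the list alone; median difference 1.15), with AURKA at 3.71 ± 0.10, PTTG1 at 2.01 ± 0.09, KIF11 at 1.64 ± 0.10 and CKAP2 at 1.46 ± 0.08. For the mitosis list camera gave adjusted p = 1.78e-20, and adjusted p = 0.0866 with an estimated correlation. Of 33 replication genes 31 were higher and 2 did not pass (31 higher adjusted over the list alone; median 0.90), such as RRM2 (1.69 ± 0.11) and MCM7 (1.14 ± 0.09). The replication list had camera adjusted p = 2.3e-09, and adjusted p = 0.0866 with an estimated correlation. Of 18 FGF and ERK feedback genes 11 were higher, 3 lower and 4 did not pass (12 and 3 adjusted over the list alone; median 0.64), SPRED2 (2.38 ± 0.10) and ETV4 (2.86 ± 0.16) higher, and IER3 (-0.78 ± 0.06), DUSP4 (-0.89 ± 0.08) and DUSP5 (-1.0 ± 0.10) lower. For the FGF and ERK list camera gave adjusted p = 5.75e-05, and adjusted p = 0.396 with an estimated correlation. Of 29 nucleolar MYC targets 17 were higher, 1 lower and 11 did not pass (19 and 1 adjusted over the list alone; median 0.26), WDR12 (1.23 ± 0.08) and ODC1 (0.76 ± 0.06) higher and PPAN (-0.36 ± 0.09) lower. The nucleolar MYC list had camera adjusted p = 0.0185, and adjusted p = 0.396 with an estimated correlation. The Notch list did not pass (12 of 27 higher, 5 lower and 10 not passing; 13 and 5 adjusted over the list alone; camera adjusted p = 0.0532), although RBPJ (1.53 ± 0.08), LFNG (1.36 ± 0.09) and HES6 (3.77 ± 0.29) did.

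Lists that were lower with the fusion than with HEY1 held 8 of 14 epithelial genes, with 6 not passing (8 adjusted over the list alone; median -1.14), among them KRT7 (-2.13 ± 0.08), KRT18 (-1.64 ± 0.06), KRT19 (-1.11 ± 0.09) and KRT8 (-0.81 ± 0.07). For the epithelial list camera gave adjusted p = 6.59e-06, and adjusted p = 0.0866 with an estimated correlation. Of 21 YAP targets 15 were lower, 1 higher and 5 did not pass (15 and 1 adjusted over the list alone; median -0.44), with ANKRD1 (-2.21 ± 0.07), IGFBP3 (-2.11 ± 0.07) and GADD45A (-1.40 ± 0.08) lower and AXL (0.54 ± 0.08) higher. The YAP target list had camera adjusted p = 4.95e-09, and adjusted p = 0.396 with an estimated correlation. In the smooth muscle list 13 of 20 were lower and 7 did not pass (16 lower adjusted over the list alone; median -0.46), such as LMOD1 (-2.58 ± 0.09) and CNN1 (-1.75 ± 0.07). For the smooth muscle list camera gave adjusted p = 8.88e-09, and adjusted p = 0.175 with an estimated correlation. Of 31 hypoxia genes 23 were lower, 4 higher and 4 did not pass (24 and 5 adjusted over the list alone; median -0.46), with CA9 (-1.91 ± 0.11), PFKFB4 (-1.51 ± 0.07) and HK2 (-1.36 ± 0.07) lower and NDRG1 (2.37 ± 0.07), ALDOA, VEGFA and PFKFB3 higher. The hypoxia list had camera adjusted p = 4.79e-08, and adjusted p = 0.0866 with an estimated correlation.

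Genes lowered by HEY1 induction, 1397 in number, were tested as a set with the fusion. Their median log2 change was 0.12. Of them, 646 rose, 392 fell and 359 did not pass, against 25.6% higher and 24.1% lower among all genes (camera p = 5.39e-05, and p = 0.0852 with an estimated correlation). The 1375 genes raised by HEY1, without HEY1 itself, had a median of -0.22 with the fusion. Of these, 701 fell, 296 rose and 378 did not pass (camera p = 1.16e-05, and p = 0.00667 with an estimated correlation). Independent lists of these sizes would share 357 genes lowered by HEY1 and raised by the fusion and 331 of the reverse kind. Genes raised by NCOA2, 561 in number without NCOA2 itself, also had a median of -0.22 with the fusion, and 292 fell and 170 rose, where independent lists would share 135 and 143 (camera p = 0.0314, and p = 0.351 with an estimated correlation). The 407 genes lowered by NCOA2 had a median of -0.11, with 187 lower and 132 higher against 98.1 and 104 (camera p = 0.229, and p = 0.323 with an estimated correlation). The sets come from the same series, so they are not independent evidence of the direction. Across genes, which are not independent, log2 changes with the fusion and with HEY1 correlated with r = -0.045 (rho = -0.125), those with the fusion and NCOA2 with r = -0.006 (rho = -0.037), and those with HEY1 and NCOA2 with r = 0.070 (rho = -0.023). The first of these r was 0.014 and 0.0032 without uninduced replicate 1 or 2 of the HEY1 line, the second 0.045 and 0.055 without uninduced replicate 1 or 2 of the NCOA2 line, and the third 0.015 without induced replicate 1 of the NCOA2 line.

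**Figure D4:**
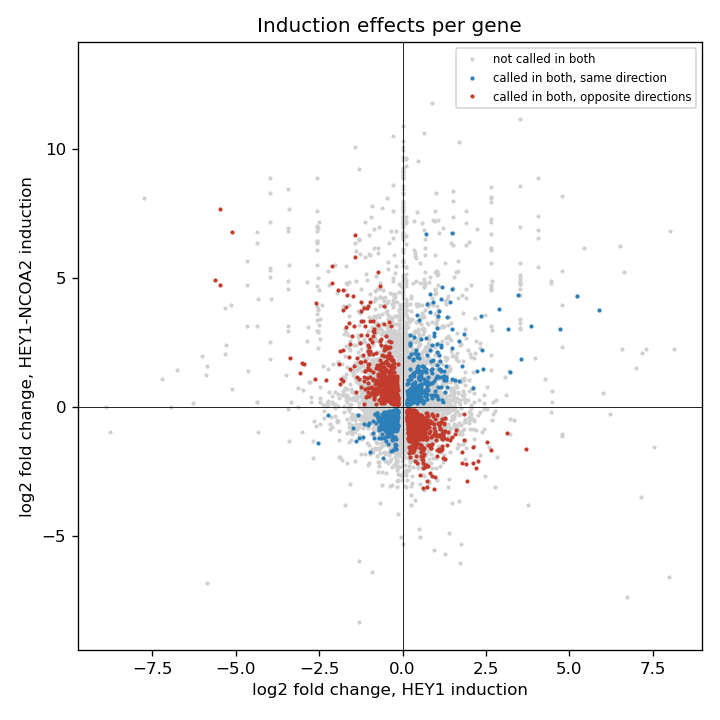
Log2 change of each tested gene except HEY1 and NCOA2 with HEY1 induction (horizontal axis) and with fusion induction (vertical axis); blue points were called in both in the same direction, red points in both in opposite directions, and grey points not in both. Opposite calls numbered 646 and 701, same-direction calls 392 lower and 296 higher. Vertical stripes are genes with almost no counts in the HEY1 line, whose fitted change depends on the prior count.

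The difference between the fusion and HEY1 passed for 7420 genes, 3730 higher and 3690 lower with the fusion, and 4 lists passed camera in each direction, of which 0 held with an estimated correlation (2 higher and 3 lower at an unadjusted p under 0.05). On the TPM scale with a pseudocount of 1, 4045 genes were higher and 1866 lower and the medians of the epithelial and YAP lists were -0.29 and -0.28. Lists numbered 9 higher without induced replicate 1 of the HEY1 line and 7 higher and 8 lower without induced replicate 2 of the fusion line. Calls ended for NRARP with DESeq2, TRIM67 without uninduced replicate 1 of the HEY1 line (adjusted p = 0.0541), SOX9 in 5 settings, VEGFA in 6, PFKFB3 in 11 and CDKN1A in 12, the last at adjusted p = 0.177 without uninduced replicate 2 of the fusion line.

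The fusion and NCOA2 were compared in the same way, since NCOA2 is the other part of the fusion. CEMIP, which degrades hyaluronan, fell from 2969 to 679 CPM with the fusion and stood at 3163 and 5336 CPM without and with NCOA2 induction (log2 difference -2.88 ± 0.08, adjusted p = 1.85e-14), and the lipid receptor S1PR1 differed by -2.75 ± 0.13. GPRC5A (-3.29 ± 0.09), SLC7A14 (-3.21 ± 0.11), PADI2, which converts arginine to citrulline (-3.19 ± 0.22), DEPP1 (-3.10 ± 0.09), MGAM (-3.09 ± 0.16), MGARP (-3.0 ± 0.06), TMEM40 (-2.65 ± 0.08) and RASGRP1 (-2.60 ± 0.09) were also lower. Adjusted p of these 10 lay between 5.61e-16 for MGARP and 1.57e-09 for PADI2. RASD1 (9.04 ± 0.63), PGM5 (8.55 ± 0.77), TRIM67 (8.41 ± 0.81), ILDR2 (8.08 ± 0.78) and RGCC (8.07 ± 0.45) were higher. LEF1, NGFR, NDNF, TH and SLCO2B1 were higher too, with at most 3 counts behind 1 group or more. TH and SLCO2B1, a transporter of organic anions, stood at 6.40 and 6.10 CPM in induced fusion cells and 0.00926 and 0.0105 CPM in induced NCOA2 cells. Adjusted p of these 10 lay between 1.34e-10 for RGCC and 0.0109 for LEF1.

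Fixed genes were mostly higher with the fusion than with NCOA2: HES1 by 5.52 ± 0.34 (adjusted p = 3.99e-10), PDGFB by 5.13 ± 0.49 (adjusted p = 1.39e-07) and BCL2 by 3.15 ± 0.49 (adjusted p = 4.69e-05). CCND1 was higher by 2.28 ± 0.10 (adjusted p = 2.46e-11), NRARP by 2.0 ± 0.41 (adjusted p = 0.000695) and PDGFRA by 1.93 ± 0.07 (adjusted p = 6.98e-13). Smaller differences were those of SOX4 (0.93 ± 0.11, adjusted p = 7.95e-06), SOX9 (0.33 ± 0.12, adjusted p = 0.0402) and PDGFRB (0.27 ± 0.06, adjusted p = 0.00145). MYC (0.26 ± 0.07, adjusted p = 0.00488) and CDKN1A (-0.33 ± 0.06, adjusted p = 0.000306) also differed, and RUNX2 did not pass (0.21, adjusted p = 0.0588). The difference passed for 6837 genes, 3446 higher and 3391 lower. On the TPM scale with a pseudocount of 1, 2981 genes were higher and 1821 lower. Calls ended for LEF1 without uninduced replicate 2 of the NCOA2 line (adjusted p = 1), NDNF without its uninduced replicate 1 (adjusted p = 0.990), and SOX9 in 10 settings.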

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

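The 3 tests of the overlaps in this part were written down before their results were seen. Each value here was singled out by a tested difference between constructs' effects. Genes called in opposite directions with the fusion and with HEY1 numbered 1347. Of these, HEY1 lowered 646 and raised 701, where independent lists would share 357 and 331. The difference passed for all, which opposite calls nearly ensure. Among them, chosen after their values were seen, LOXL4 (4.79 with the fusion, -2.11 with HEY1), the transporter SLC16A6 (6.67 and -1.42), LRRC15 (5.80 and -1.42) and the ligand WNT10B (4.30 and -1.47) rose with the fusion and fell with HEY1, and RAB7B (-2.85 and 1.93) and the aryl hydrocarbon receptor target CYP1A1 (-1.65 and 3.70) did the reverse.

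A technical candidate explanation for these opposite calls is that well measured genes are called in every comparison. It is argued against: 1000 random gene sets matched on mean expression held on average 368 and at most 425 genes called higher with the fusion against the 646 observed, and on average 391 and at most 450 called lower against the 701. Taking out the replication and mitosis lists, which hold 43 of the 646 genes, left a ratio of observed to independent overlap of 1.762 against 1.81, but with 73 members it could not have gone below 1.71, so that test decides nothing. A response to doxycycline itself would be shared by the lines and give calls in the same direction, which numbered 392 lower (337 for independent lists, 370 to 468 in matched sets) and 296 higher (351, and 315 to 409), while HEY1 and NCOA2 shared 149 higher and 76 lower genes against 42.4 and 31.3, but also 102 and 91 called in opposite directions against 43.1 and 30.8. Opposite action of constructs (or lines) on shared genes stays open as a hypothesis. Whether it is particular to HEY1 is open, lacking matched sets for NCOA2. With the fusion 292 genes raised by NCOA2 fell (135 for independent lists), but so did 187 lowered by NCOA2 (98.1).

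Between the fusion and HEY1, the list medians differed by 1.15 for mitosis, 0.90 for replication, 0.64 for FGF and ERK feedback, 0.26 for nucleolar MYC targets, -0.44 for YAP targets, -0.46 for smooth muscle, -0.46 for hypoxia and glycolysis and -1.14 for epithelial genes. With an estimated correlation 0 of these 8 list calls held (adjusted p = 0.0866 to 0.396). Of the genes fixed in advance, the log2 difference was 7.60 for HES1, 5.64 for PDGFB, 3.39 for BCL2, 3.20 for CCND1, 1.62 for SOX4, 1.62 for NRARP, 1.41 for PDGFRA, 0.81 for RUNX2, 0.48 for PDGFRB, 0.17 for CDKN1A and -0.43 for SOX9. Of the 39 genes with the largest changes in either induction, 35 differed. Between the fusion and NCOA2, the log2 difference was 5.52 for HES1, 5.13 for PDGFB, 3.15 for BCL2, 2.28 for CCND1, 2.0 for NRARP, 1.93 for PDGFRA, 0.93 for SOX4, 0.33 for SOX9, 0.27 for PDGFRB, 0.26 for MYC and -0.33 for CDKN1A. Of the 38 genes with the largest changes 31 differed, against 37.6% of all tested genes, which their choice nearly ensures too. Calls ended for SOX9 in 5 settings against HEY1 and 10 against NCOA2, CDKN1A in 12 against HEY1, and NRARP against HEY1 with DESeq2.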

How the results depend on the processing

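Every alternative was planned. The medians of the sets raised and lowered by HEY1 kept their direction with the fusion in each edgeR fit. They were not run with DESeq2, limma-voom, TPM or glmTreat. Correlations of effects across genes turned. So did the balance of higher and lower genes where it was near even, as with RLE size factors (1465 higher and 1298 lower with HEY1, 3698 and 3729 for the fusion minus HEY1), DESeq2 (1306 and 1152, 3235 and 3305), and without uninduced replicate 1 of the fusion line (3047 and 3122 for the fusion minus NCOA2). The correlation of HEY1 with NCOA2, 0.070, was -0.00168 with the libraries of the 2 lines alone and 0.016 without a filter on low counts. Counts of changed genes are given as higher, then lower. With a pseudocount of 1 on the TPM scale the moved counts were 2355 lower with the fusion, 530 higher with HEY1, 246 and 118 with NCOA2, 1866 lower for the fusion minus HEY1 and 1821 lower for the fusion minus NCOA2. With a pseudocount of 0.1 they were 2393, 523, 229 and 123, 1891 and 1865. The share of higher calls moved from 51.5% to 64.6% and 64.0% with the fusion, from 49.6% to 33.4% and 31.9% with HEY1, from 50.3% to 68.4% and 68.0% for the fusion minus HEY1, and from 50.4% to 62.1% and 61.05% for the fusion minus NCOA2. The cause was not tested; the median of all genes with the fusion was 0.0741 and 0.0864 on the TPM scale and 0.00556 on counts. Fits to the line's own libraries gave 860 and 764 genes with HEY1 and 1376 and 1071 with NCOA2, each with a spread estimated from fewer libraries. The test against a 1.2-fold change, which by construction calls fewer genes, gave 2788 and 2322 with the fusion, 349 and 295 with HEY1, 136 and 46 with NCOA2, 2329 and 2236 for the fusion minus HEY1, and 2135 and 1975 for the fusion minus NCOA2. With an estimated correlation, camera called 0 lists higher and 0 lower with the fusion, 1 and 1 with HEY1, 2 and 0 with NCOA2, and 0 and 0 for the fusion minus HEY1. At an unadjusted p under 0.05 it gave 12 and 4, 5 and 4, 4 and 2, and 2 and 3. The set lowered by HEY1 (median 0.12) had camera p = 0.0852 with an estimated correlation with the fusion; the estimate widens the test by construction. With fry, 32 lists were higher with the fusion, 5 lower with NCOA2, and 23 higher and 9 lower for the fusion minus HEY1; fry asks another question, whether a list moves 1 way.

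The replicate numbers were not found to pair the samples: the deviations of same-numbered uninduced and induced libraries correlated with 0.417, 0.030 and 0.141 in the fusion, HEY1 and NCOA2 lines, where each had to exceed 0.1. With the number as a block shared by all lines, 4756 genes rose and 4482 fell with the fusion, 1538 and 1491 with HEY1 and 618 and 464 with NCOA2, and 9 lists were higher with HEY1 instead of 14. With a block within each line the counts were 4801 and 4560, 1540 and 1592, and 719 and 483.

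Leaving out each library in turn, where the lone library of a group is assumed to vary like the other groups, gave ranges of 3879 to 4920 higher and 3668 to 4650 lower genes with the fusion, 834 to 1394 and 824 to 1485 with HEY1, 256 to 694 and 141 to 529 with NCOA2, 3206 to 3592 and 3294 to 3663 for the fusion minus HEY1, and 2794 to 3670 and 2841 to 3644 for the fusion minus NCOA2. The lowest counts with HEY1 came without its uninduced replicate 1, and those with NCOA2 without its uninduced replicate 2. Genes that differed among uninduced lines ranged from 5390 to 8610. Lists ranged from 17 to 19 higher and 7 to 9 lower with the fusion, and 10 to 17 and 4 to 5 with HEY1. They ranged from 5 to 8 and 7 to 11 with NCOA2, and 4 to 9 and 4 to 8 for the fusion minus HEY1. The median of genes lowered by HEY1 ranged from 0.067 to 0.167 with the fusion and that of genes raised by HEY1 from -0.250 to -0.188. Correlations ranged from -0.092 to 0.014 for the fusion with HEY1 and from -0.081 to 0.055 for the fusion with NCOA2. That of HEY1 with NCOA2 ranged from 0.015 to 0.065.

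Results for named genes, over all contrasts and settings, numbered 11718, of which 11142 kept their direction and side of the threshold, 492 lost and 80 gained a call with the same direction, and 4 changed sign. Those 4 were SEMA3F with the fusion, -0.29 on counts and 0.013 and 0.014 on the TPM scale with pseudocounts of 1 and 0.1 (adjusted p = 0.932 and 0.93), and RFNG for the fusion minus HEY1, -0.24 on counts and 0.045 and 0.047 on the TPM scale (adjusted p = 0.746 and 0.742); the cause was not tested. Depth limited genes that were near 0 before induction: 3 counts over 2 libraries are the floor behind the bound for LEF1, and 5 counts in induced libraries lay behind the fall of HES1 with HEY1.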

Other observations

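The tests of HEY1 reads carried with the fusion transcript, of induced HEY1 reads spread over libraries, and the comparison that kept called genes in were chosen only after the result was seen. Fusion induction also moved lists not yet described. Of 54 axon guidance genes 30 rose, 17 fell and 7 did not pass (30 and 18 adjusted over the list alone; median 0.45, and 0.20 on the TPM scale; camera adjusted p = 2.18e-05, and adjusted p = 0.163 with an estimated correlation). The semaphorin receptor PLXNC1 rose by 6.72 ± 0.10, the ephrin receptor EPHB3 by 6.17 ± 0.18, the guidance cue SLIT2 by 2.38 ± 0.08 and SEMA7A by 1.90 ± 0.06, and NTN4 (-1.17 ± 0.05), SEMA5A (-1.04 ± 0.07) and SEMA3B (-1.37 ± 0.10) fell. Of 13 genes of retinoic acid signalling 7 rose, 3 fell and 3 did not pass (8 and 3 adjusted over the list alone; median 0.65, and 0.32 on the TPM scale; camera adjusted p = 0.0392, and adjusted p = 0.151 with an estimated correlation): CYP26B1, which degrades retinoic acid, rose by 3.41 ± 0.16, and the receptor RARG by 0.77 ± 0.05, while RARA (-0.65 ± 0.06), CRABP2 (-0.67 ± 0.09) and RXRB (-0.30 ± 0.05) fell. Of 23 immediate early genes 14 rose, 6 fell and 3 did not pass (14 and 6 adjusted over the list alone; median 0.40; camera adjusted p = 0.012, and adjusted p = 0.551 with an estimated correlation), EGR3 (6.34 ± 0.12), NR4A2 (4.39 ± 0.21) and KLF4 (1.84 ± 0.08) rising and CCN1 (-0.53), ATF3 (-0.46) and BTG2 (-0.43) falling. Of 29 nucleolar MYC targets 25 rose, 1 fell and 3 did not pass (25 and 1 adjusted over the list alone; median 0.25, and 0.38 on the TPM scale; camera adjusted p = 0.00177, and adjusted p = 0.136 with an estimated correlation), such as WDR12 (1.03 ± 0.05) and RRS1 (1.04 ± 0.08). Of 21 oxidative stress genes 11 fell, 7 rose and 3 did not pass (11 and 7 adjusted over the list alone; median -0.20, and -0.10 on the TPM scale; camera adjusted p = 0.0281, and adjusted p = 0.249 with an estimated correlation), TXNRD1 (-1.25 ± 0.04) and ME1 (-0.70 ± 0.06) lower and GCLC (0.86 ± 0.06) higher.

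With HEY1, 7 of 25 cholesterol synthesis genes rose, 1 fell and 17 did not pass (9 and 1 adjusted over the list alone; median 0.09; camera adjusted p = 0.00431, and adjusted p = 0.277 with an estimated correlation). CYP51A1, which NCOA2 raised too, rose by 0.38 ± 0.05, and EBP fell (-0.35 ± 0.08). With NCOA2, 3 of 23 immediate early genes fell and 20 did not pass (7 fell adjusted over the list alone; median -0.18, and -0.11 on the TPM scale; camera adjusted p = 0.000304, and adjusted p = 0.613 with an estimated correlation), EGR1 by -0.48 ± 0.08, EGR2 by -1.17 ± 0.21 and ATF3 by -0.22 ± 0.06. The calls for EGR2 and ATF3 ended on the TPM scale, and without induced replicate 2 of the line (adjusted p = 0.0560 and 0.118); that for ATF3 also ended without each of the line's other libraries, at adjusted p up to 0.253 without uninduced replicate 2. Genes raised by all 3 constructs numbered 38, where independent lists would share 10.8, and genes lowered by all 3 numbered 27 against 7.53. Opposite calls with HEY1 and NCOA2 exceeded independent lists too. Only EFHD1, chosen after its values were seen, changed over 2-fold in each line (1.48 ± 0.16 with the fusion, 1.08 ± 0.20 with HEY1 and 1.1 ± 0.18 with NCOA2). Genes that went from under 0.1 to at least 1 CPM numbered 89 with the fusion, 83 of them protein coding, 0 with HEY1 and 1 with NCOA2.

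Of the 534 genes that the fusion raised at least 8-fold, 19 were also higher with NCOA2, where independent lists would share 16.5, which is hardly an excess. They include the growth factor IGF2 (6.81 ± 0.15 and 1.68 ± 0.32), SOST (6.99 and 2.22 ± 0.35) and the neurofilament NEFM (5.65 and 1.59). Reads or cells of induced fusion libraries in the induced NCOA2 libraries could raise such genes; the 19 rose there by 0.814% to 18.5% of their induced fusion level, and 84 other genes specific to the fusion libraries by a median of 0.0518% with an upper quartile of 0.386%. That test cannot decide, since its 84 genes left out those called with NCOA2, and with these kept in the upper quartile over 97 genes was 1.03%. HEY1 itself, which the fusion transcript would carry, had 48 counts in induced and 47 in uninduced NCOA2 libraries, an excess of at most 0.114% of its induced fusion level, below the 0.814% of the lowest of the 19, which argues against a carry-over of that transcript.

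HEY1 stood higher in the uninduced HEY1 line than in the uninduced NCOA2 line, by 3.93 ± 0.19 on the log2 scale. A spread of reads from induced HEY1 libraries over all libraries is argued against, since the highest uninduced NCOA2 library held 0.0731 of the HEY1 level of the lowest uninduced HEY1 library. Leaky expression of the construct that already acts on its targets stays a candidate explanation. The 1397 genes lowered by HEY1 induction had a median difference of -0.043 between the uninduced HEY1 and fusion lines, 124 lower and 42 higher, although the shared uninduced libraries push the other way. This comparison cannot tell which of the 2 lines moved. HEY1 was also higher in the uninduced fusion line than in the uninduced NCOA2 line (1.26 ± 0.26). Of the same 1397 genes, 646 rose and 392 fell with the fusion, so a leak of the fusion could give the same sign. Camera gave p = 0.000863 with the preset correlation and p = 0.142 with an estimated correlation. The 1375 genes raised by HEY1 did not pass as a set (median 0.00925, camera p = 0.453 with the preset correlation). No biological explanation was tested.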
